A study of Mus musculus with 9 samples.

How the data were processed

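Total RNA of day 21 mouse oocytes was sequenced after the nucleus of each oocyte had been separated from its cytoplasm by micromanipulation, with 10 nuclei or cytoplasms pooled per sample. The labels list 9 libraries: 3 of wild-type (WT) nuclei, 2 of WT cytoplasms, 2 of MTR4-null nuclei and 2 of MTR4-null cytoplasms. Per the labels' protocols, RNA was taken up in TRIzol, ribosomal RNA was removed with a depletion module, cDNA of 300 to 400 bp was selected, and libraries were read as paired ends of 150 bp on an Illumina instrument. Total RNA libraries of this kind hold RNAs without a poly(A) tail as well as mRNA.

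The authors deposited a single table of FPKM (fragments scaled to transcript length and to the total of mapped fragments), with 23235 gene symbols and 4 columns, 1 for each combination of genotype and compartment. TopHat2 2.1.1, Cufflinks 2.2.1 and the genome build mm9 appear in the submitters' processing notes, which give neither their settings nor the order of steps. Each deposited column is therefore a value of a whole group, called here the authors' mean FPKM, and single libraries were not analysed here. Of the values above 0, 58.9% in the WT nucleus, 56.0% in the MTR4-null nucleus, 55.9% in the WT cytoplasm and 39.0% in the MTR4-null cytoplasm end in repeated decimals of 1/3 or 2/3, against 0.2% by chance, which is the pattern of means of 3 values (or of a multiple of 3). The labels list 3 libraries only for the WT nucleus, so the number of values behind each mean is uncertain. The last row of the table has no gene name and equals the sum of the others, so that it holds 50% of all values. It was left out.

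Because the columns carry no replicates, none of the planned tests could be run: no moderated linear model, no gene set test and no comparison with the spread between libraries. No p-value, SD or n is given, and each difference describes these 4 columns without a replicate check. Differences were computed on log2(FPKM + 1), a scale with a pseudocount of 1 that understates differences of genes with low values. The planned filter, an FPKM of at least 1 in at least 2 libraries, became an FPKM of at least 1 in at least 1 of the 4 columns, which kept 14270 genes. Genes at least 2-fold apart on the log2(FPKM + 1) scale were counted for 6 comparisons: genotype in the nucleus, genotype in the cytoplasm, compartment in WT, compartment in MTR4-null, the difference between those compartment ratios, and genotype averaged over the compartments.

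Apart from list members, the genes named were chosen by the size parts of a rule set before the data were examined, since its parts on p-values and overlap between libraries could not be applied. For each genotype comparison these were the 8 genes with the largest log2 difference in each direction among genes at 5 FPKM or more in the higher column, and the 3 largest in each direction among predicted gene models and small RNA genes. Of these, 1 gene is not reported here. For the compartment comparisons and the difference of ratios the 5 largest in each direction were taken, again without predicted gene models and small RNA genes as told by symbol. The symbols set aside do not cover Rmrp, Rpph1, Terc and the Rprl genes. These rank among the other genes although the list of small nuclear and nucleolar RNAs holds them. Up to 4 members with the largest difference at 5 FPKM or more were taken from each of 30 gene lists fixed beforehand, of which 29 had at least 5 measured members. The preset rule ranked list members by p-value, so ranking by size was a substitute that picks the most extreme members. The list of mitochondrially encoded genes had 0 members in the table. Other genes in the text were chosen after their values were seen. For each list, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. Its percentile describes these columns and is not a test. On simulated columns for the nuclear genotype comparison with 12489 genes, 100% of genes planted at 4-fold, 9% of genes planted at 1.5-fold and 0.187% of unplanted genes were counted as at least 2-fold apart. In the same simulation 8% of random lists lay outside the central 95%, so a few of 29 lists can do so with no planted difference. The simulated columns were drawn from the WT nucleus values with an assumed noise, as the spread between libraries is unknown. These shares therefore check the counting and are not error rates of the data.

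FPKM is a relative measure, and the read depth behind it is unknown: low values are estimates averaged over libraries and do not step by whole reads. The columns sum to 854286 in the WT nucleus, 880989 in the MTR4-null nucleus, 416740 in the WT cytoplasm and 433013 in the MTR4-null cytoplasm. Genes of small RNAs, most of them shorter than the selected fragments, make up 57.7%, 53.4%, 4.09% and 39.0% of these sums in the same order, and Scarna2 alone, whose 414 nt are close to the fragment size, 42.3%, 42.1% and 23.1% of those of the WT nucleus, MTR4-null nucleus and MTR4-null cytoplasm. FPKM of genes shorter than the fragments is unreliable and can be inflated. An exact 0 can be a failed estimate, so such a gene is only described as listed at 0. How reads of near-identical copies (histone, ribosomal protein, zinc finger and Oog genes, for example) and of overlapping genes on opposite strands were shared is not given in the sources used here, and values of such genes are uncertain one by one.

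Alternatives set beforehand were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, quantile normalization, rescaling of the columns to equal sums, and centring by the median log ratio over genes at 1 FPKM or more in every column. Added after seeing the data were a filter of 1 FPKM in 2 of the 4 columns, leaving out small RNA genes, rescaling to the sum without them, and lists matched on length and GC content. Exon number, length and GC content came from the longest basic transcript of each gene in GENCODE M21 on assembly GRCm38, matched through current and older symbols. As this is not the build in the processing notes, no coordinates are given. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.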

Results

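The data are 4 genome-wide columns of the authors' mean FPKM, from nuclei and cytoplasms of day 21 mouse oocytes with and without MTR4, the RNA helicase that feeds nuclear transcripts to the exosome for degradation. At least 1 FPKM was reached by 12135 genes in the WT nucleus, 12530 in the MTR4-null nucleus, 11023 in the WT cytoplasm and 11700 in the MTR4-null cytoplasm. The deposited table has 1 column per group and no replicates, so each difference below is a difference between these columns whose error is unknown. Across the 14270 genes kept, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.79 between the nuclei of both genotypes and 0.83 between their cytoplasms. Within a genotype, nucleus and cytoplasm had an r of 0.88 in WT and 0.92 in MTR4-null.

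The transcript of Mtr4 itself, listed under its older symbol Skiv2l2, checks the labels. It stood at 16.2 FPKM in the WT nucleus and 2.91 FPKM in the MTR4-null nucleus, or 17.97% of WT. In the cytoplasm it stood at 21.6 FPKM in WT and 2.51 FPKM in MTR4-null, or 11.6% of WT. Which exons the null allele lacks is not given in the sources used here, so part of the remaining signal can come from parts of the gene outside the deletion.

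The first comparison asks how RNA of the nuclear samples differs without MTR4. In WT, oocyte mRNAs had FPKM in these samples much like those in the cytoplasm. Of 44 maternal effect genes and 35 meiotic maturation genes, 0 were at least 2-fold apart between the WT compartments. How much cytoplasm the nuclear samples held cannot be told from these columns, so a difference in them need not be one of nuclear RNA. Histone genes dominated the higher end. Hist1h2ag was at 0.948 FPKM in the WT nucleus and 146 FPKM in the MTR4-null nucleus, Hist1h3c at 1.69 and 196, Hist1h4k at 2.09 and 175, Hist1h4f at 3.86 and 230.4, Hist1h1b at 0.136 and 44.0, and Hist1h2ai at 0.169 and 45.0. The other named genes at that end were Mt1, which encodes a metal-binding metallothionein, at 2.01 and 175 FPKM, and the ribosomal protein gene Rpl26, at 0.00107 and 68.5. At the lower end stood Cox7a1, a subunit of cytochrome c oxidase, at 32.2 FPKM in WT and 0.444 in MTR4-null, the kinase gene Dclk1 at 24.9 and 0.164, the butyrophilin gene Btn1a1 at 33.0 and 0.75, Stk32a at 30.4 and 0.684, Npff at 25.9 and 0.452, the defensin gene Defb19 at 19.6 and 0.146, and the calpain gene Capn2 at 21.6 and 0.352. AF357425 was at 269 FPKM in the WT nucleus and listed at 0 in the other columns. Among gene models and small RNAs, Snord85 and Mir5131 reached 2908 and 2758 FPKM in the MTR4-null nucleus with WT at or near 0, and Mir1893 3244 against 0.0525. Snora61, Snord110 and Snord35b were at 2995, 1888 and 1744 FPKM in the WT nucleus and listed at 0 in MTR4-null.

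In total, 3417 genes were at least 2-fold higher and 1753 at least 2-fold lower in the MTR4-null nucleus. The median log2 difference over all genes was 0.21, and after centring by the median log ratio the counts were 2727 higher and 2327 lower. Differences also followed base composition: across 5 equal groups of coding genes ordered by GC content the median log2 difference went from -0.08 to 0.60 in the nucleus and from -0.51 to 0.00 in the cytoplasm.

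**Figure D1:**
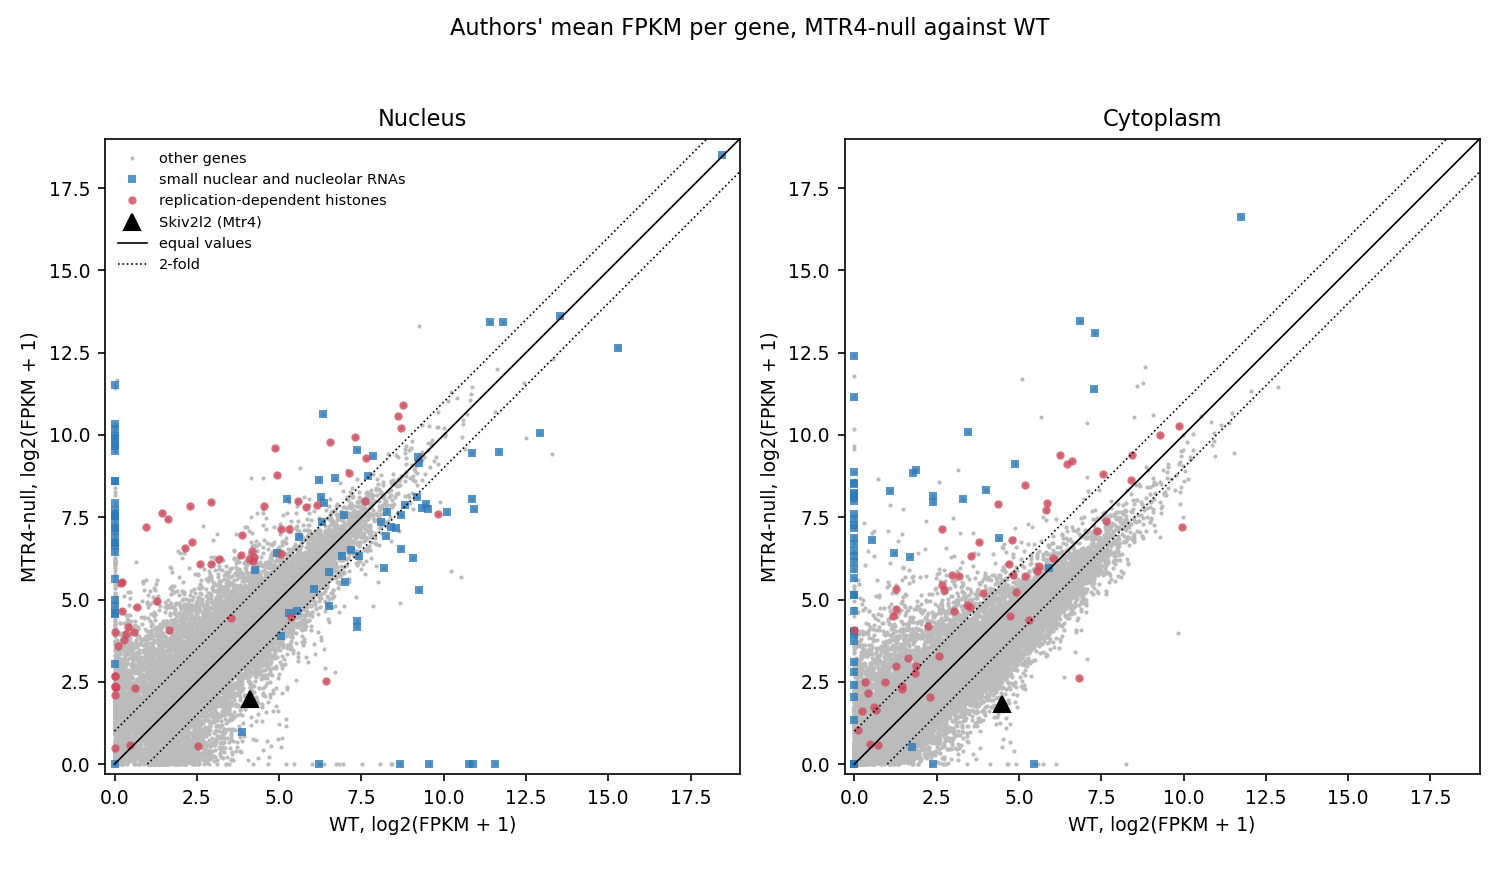
Each point is a gene, with the authors' mean log2(FPKM + 1) in WT on the horizontal axis and in MTR4-null on the vertical axis, for the nucleus (left) and the cytoplasm (right), with solid lines at equal values and dotted lines at 2-fold differences. Histone genes (red) lie mostly above the line in both panels, small nuclear and nucleolar RNAs (blue) lie on both sides in the nucleus and mostly above in the cytoplasm, and Skiv2l2 (triangle) lies below in both.

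Replication-dependent histone genes, whose mRNAs normally end without a poly(A) tail and serve DNA replication, stood apart as a group in the nucleus. Of 59 measured members, 51 were at least 2-fold higher in MTR4-null, 3 at least 2-fold lower and 5 in between. The median log2 difference was 2.52, at percentile 100 of matched random lists, and ranged from 1.93 to 3.26 over the alternatives. The summed FPKM of the list was 3580 in the WT nucleus and 12838 in the MTR4-null nucleus. The lower members were Hist2h2ac at 85.3 and 4.71 FPKM, Hist2h2bb at 910.4 and 195, and the testis linker histone Hist1h1t at 4.82 and 0.454. Slbp, which encodes the protein that binds the end of histone mRNA, was itself at 508 FPKM in the WT nucleus and 243 in the MTR4-null nucleus. Markers of granulosa cells, the dividing cells around the oocyte, were measured beside them: 7 of 20 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.33 at percentile 61.6. Hsd17b1 was at 0.424 and 6.15 FPKM and Kctd14 at 0.722 and 5.73, while Cyp11a1 was at 21.3 and 1.47 and Inhbb at 7.90 and 0.826.

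Genes of ribosomal proteins also lay above matched lists in the nucleus, with a median of 0.51 at percentile 100. Of 83 members, 14 were at least 2-fold higher and 1, Rps27, at least 2-fold lower at 14.1 and 3.99 FPKM, and after centring 7 were higher and 1 lower. Rps3 was at 13.1 and 51.9 FPKM and Rpl37a at 66.2 and 206. Zinc finger genes of the Zfp, Zkscan and Zscan series, many of them KRAB repressors, had a median of 0.59 at percentile 100, with 120 of 329 at least 2-fold higher and 28 lower, or 98 and 38 after centring. Zfp622 was at 0.873 and 38.0 FPKM, Zfp623 at 1.46 and 32.3, Zscan4d, of a family known from the 2-cell embryo, at 0.239 and 15.1, and Zfp935 at 1.42 and 28.8. MicroRNA genes had a median of 3.71 at percentile 100, with 77 of 128 at least 2-fold higher and 27 lower, but 69 were listed at 0 in WT alone, and the 36 above 0 in both columns had a median of -0.34. Small nuclear and nucleolar RNA genes went both ways, with 45 of 92 higher and 32 lower. Their median of 0.35 lay at percentile 93.0, but at 5.02 with GC content and length matched too. The 55 above 0 in both columns had a median of -0.89. Nuclear-encoded genes of oxidative phosphorylation, with a median of 0.31 at percentile 97.3, lay inside the central 95% (percentile 73.4 with GC content and length matched too), with 21 of 88 higher and 4 lower, or 13 and 5 after centring: Uqcrb was at 6.92 and 67.6 FPKM and Atp5g3 at 16.1 and 136.

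The machinery of nuclear RNA decay did not stand apart. Among 28 genes of the exosome and its nuclear cofactors, 7 were at least 2-fold higher and 1, Skiv2l2, lower, with a median of 0.16 at percentile 42.1; centring turned these to 3 higher, 4 lower and -0.04. Exosc6, an exosome ring subunit, was at 6.60 and 77.9 FPKM, the cap-binding gene Ncbp1 at 5.16 and 15.1, and Exosc7 at 26.7 and 61.5. Of 17 genes of the cytoplasmic exosome and decay from the 5-prime end, 3 were higher and 1 lower (median 0.22, percentile 58.9, or 2 higher, 2 lower and 0.02 after centring), Wdr61 being at 3.77 and 61.4 FPKM. Lists of the RNA machinery lay inside the central 95% as well. Splicing factors had a median of 0.27 (percentile 86.6) and mRNA export of 0.22 (percentile 68.6). Centring turned the medians of poly(A) metabolism (0.15, percentile 51.3), ribosome biogenesis (0.12) and translation factors (0.19, percentile 73.8) to -0.05, -0.08 and -0.01. So did the oocyte lists. Meiotic maturation genes had a median of -0.06 (percentile 14.7). Centring turned the medians of maternal effect genes (0.04), of oocyte transcription factors and growth signals (0.12) and of zona pellucida and secreted factors (0.19) to -0.16, -0.07 and -0.01. Zp2 was at 1116 FPKM in the WT nucleus and 2082 in the MTR4-null nucleus, Nlrp5 at 314 and 690.0, and Ccnb3, a meiotic cyclin, at 19.4 and 2.59.

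The second comparison asks the same of the cytoplasm. Here 2 RNAs that normally reside in the nucleus were among the 8 genes at the higher end, as their symbols are not among the small RNA symbols set aside. Rmrp, the RNA of RNase MRP, was at 115 FPKM in WT and 11312 in MTR4-null, and Rpph1, the RNA of RNase P, at 156 and 8822. Churc1 was at 0.22 and 160.2 FPKM, Mt1 at 0.447 and 128, Zfp607 at 0.343 and 88.6, the RNase gene Zc3h12a at 0.252 and 65.0, and Ccdc48 at 0.0102 and 47.8. Rplp2-ps1 was below 0.001 FPKM in WT and at 73.2 in MTR4-null. At the lower end were Btn1a1 at 28.0 FPKM in WT and 0.313 in MTR4-null, Hist2h2ac at 112 and 5.14, Stk32a at 25.2 and 0.579, Dydc2 at 21.3 and 0.439, the filament gene Bfsp1 at 21.9 and 0.711, Ccdc109b at 80.8 and 5.21, and Dclk1 at 12.02 and 0.116. Scarna17 (5452 FPKM), Mir5131 (3528 FPKM) and Snord71 (2266 FPKM) had the largest differences among small RNAs, with WT at or near 0. Mir678 and Mir207 were at 304 and 68.3 FPKM in WT and at or near 0 in MTR4-null, and Mir22 was at 911 and 14.7.

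At least 2-fold higher in the MTR4-null cytoplasm were 2135 genes, and 3047 were at least 2-fold lower. This split depended on scaling. The median log2 difference was -0.26 over all genes and -0.72 over the genes at 20 FPKM or more in every column. Centring by the median log ratio, taken over genes at 1 FPKM or more in every column, turned the split to 3528 higher and 991 lower. It left the median over all genes at 0.26. Centring on the median of all genes gave 2792 higher and 1854 lower, and quantile normalization 2119 and 2186. FPKM of genes other than small RNAs summed to 399687 in the WT cytoplasm and 264137 in the MTR4-null cytoplasm. Rescaling to that sum gave 3226 higher and 1071 lower.

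Small nuclear and nucleolar RNA genes had a median log2 difference of 3.42 in the cytoplasm, at percentile 100 of matched lists and at 1.88 to 5.38 over the alternatives. Of 92 members, 52 were at least 2-fold higher and 3 lower. Of all members 35 were listed at 0 in both columns and 35 in WT alone, and the 19 above 0 in both had a median of 5.19, with 17 at least 2-fold higher and 1 lower. Their summed FPKM was 4062 in WT and 139828 in MTR4-null. Scarna2 was at 3428 and 100235 FPKM, and Terc, the telomerase RNA, at 1.32 and 83.5. Many of these RNAs are shorter than the selected fragments. Among 11 nuclear long noncoding RNAs, 4 were higher and 1 lower (median 0.24, percentile 78.4). Malat1, a nuclear-retained RNA, was at 8.63 FPKM in the WT cytoplasm and 69.6 in the MTR4-null cytoplasm, while Airn was at 1.20 and 1.26. Genes that host small nucleolar RNAs in their introns had a median of 0.24 at percentile 96.2 (98.6 for the 16 annotated members, at a median of 0.20, with GC content and length matched too), with 5 of 18 higher and 4 lower, Snhg3 being at 0.728 and 25.6 FPKM and Hspa8 at 543 and 154.

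Histone genes were again above matched lists, with a median of 1.29 at percentile 100 and 34 of 59 at least 2-fold higher against 2 lower. Hist1h4f was at 19.5 FPKM in the WT cytoplasm and 238 in the MTR4-null cytoplasm, Hist1h2bj at 56.6 and 243. The immediate early genes, transcription factors of the first response to growth signals, had a median of 0.84 at percentile 99.4, with 6 of 16 at least 2-fold higher, 2 lower and 8 in between: Jund was at 8.15 and 129 FPKM, Ier2 at 0.154 and 13.0, Jun at 0.0733 and 6.93, and Junb at 0.44 and 8.41. Jund, Ier2 and Junb have a single exon, and of 296 such coding genes other than histones 119 were higher in this cytoplasm and 12 lower. The immediate early genes are also rich in G and C. Lists matched on GC content and length put them at percentile 96.1, inside the central 95%. Genes of the unfolded protein and integrated stress responses had a median of 0.13 at percentile 98.9, with 6 of 25 higher and 1 lower, and at 97.1, also inside, with GC content and length matched. Xbp1, a regulator of that response, was at 0.651 and 10.5 FPKM, Chac1 at 1.76 and 14.2, and Slc7a11 at 47.1 and 12.8.

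Oocyte mRNAs were mostly lower in the MTR4-null cytoplasm as deposited, to about the same extent as other abundant genes. None of 44 maternal effect genes was at least 2-fold higher and 18 were lower, with a median of -0.83 at percentile 32.4, and after centring 1 was higher and 9 lower, with a median of -0.31. Centring on all genes, which moved cytoplasmic values less, gave 0 higher, 16 lower and a median of -0.57. Npm2, a chromatin chaperone of the egg, was at 943 FPKM in WT and 306 in MTR4-null, Oog3 at 557 and 134, and Nlrp2 at 118 and 29.1. Of 35 meiotic maturation genes, 15 were lower and 1, Tex19.1, higher (median -0.84, percentile 23.3, or 3 lower, 1 higher and a median of -0.32 after centring): Plk1 was at 151 and 44.3 FPKM, Slbp at 508 and 163, and Tex19.1 at 38.0 and 157. Genes of poly(A) metabolism had a median of -0.92 at percentile 3.22 (12.1 with GC content and length matched too), with 3 of 36 higher and 11 lower, or 5 and 2 after centring. With centring on all genes they were 5 and 7. Lower as deposited were the deadenylase gene Cnot7 at 114 and 35.5 FPKM and Cpeb1 at 361 and 126. Translation factors had a median of -0.80 (percentile 8.75), oocyte transcription factors and growth signals -0.64 (percentile 44.4), oxidative phosphorylation -0.64 (percentile 67.1), the exosome and its cofactors -0.61 (percentile 42.1), cytoplasmic decay -0.61 (percentile 36.3), cytoskeleton genes -0.56 (percentile 70.6), ribosome biogenesis -0.53 (percentile 52.7), secreted oocyte factors -0.50 (percentile 84.1) and mRNA export -0.46 (percentile 88.2). The last 2 turned to 0.02 and 0.07 with centring, but to -0.24 and -0.20 with centring on all genes. Gdf9, a growth factor of the oocyte, was at 2677 FPKM in WT and 1304 in MTR4-null, and Zp3 at 1470.5 and 1540.1. Ribosomal protein genes (median -0.40) and splicing factors (median -0.41) were less far below 0 than matched lists, at percentiles 100 and 98.5, and centring put their medians at 0.12 and 0.11. Centring on all genes put them at -0.14 and -0.15. Granulosa markers had 0 of 20 members higher and 3 lower (median -0.21, percentile 16.01, 0.32 after centring).

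**Figure D2:**
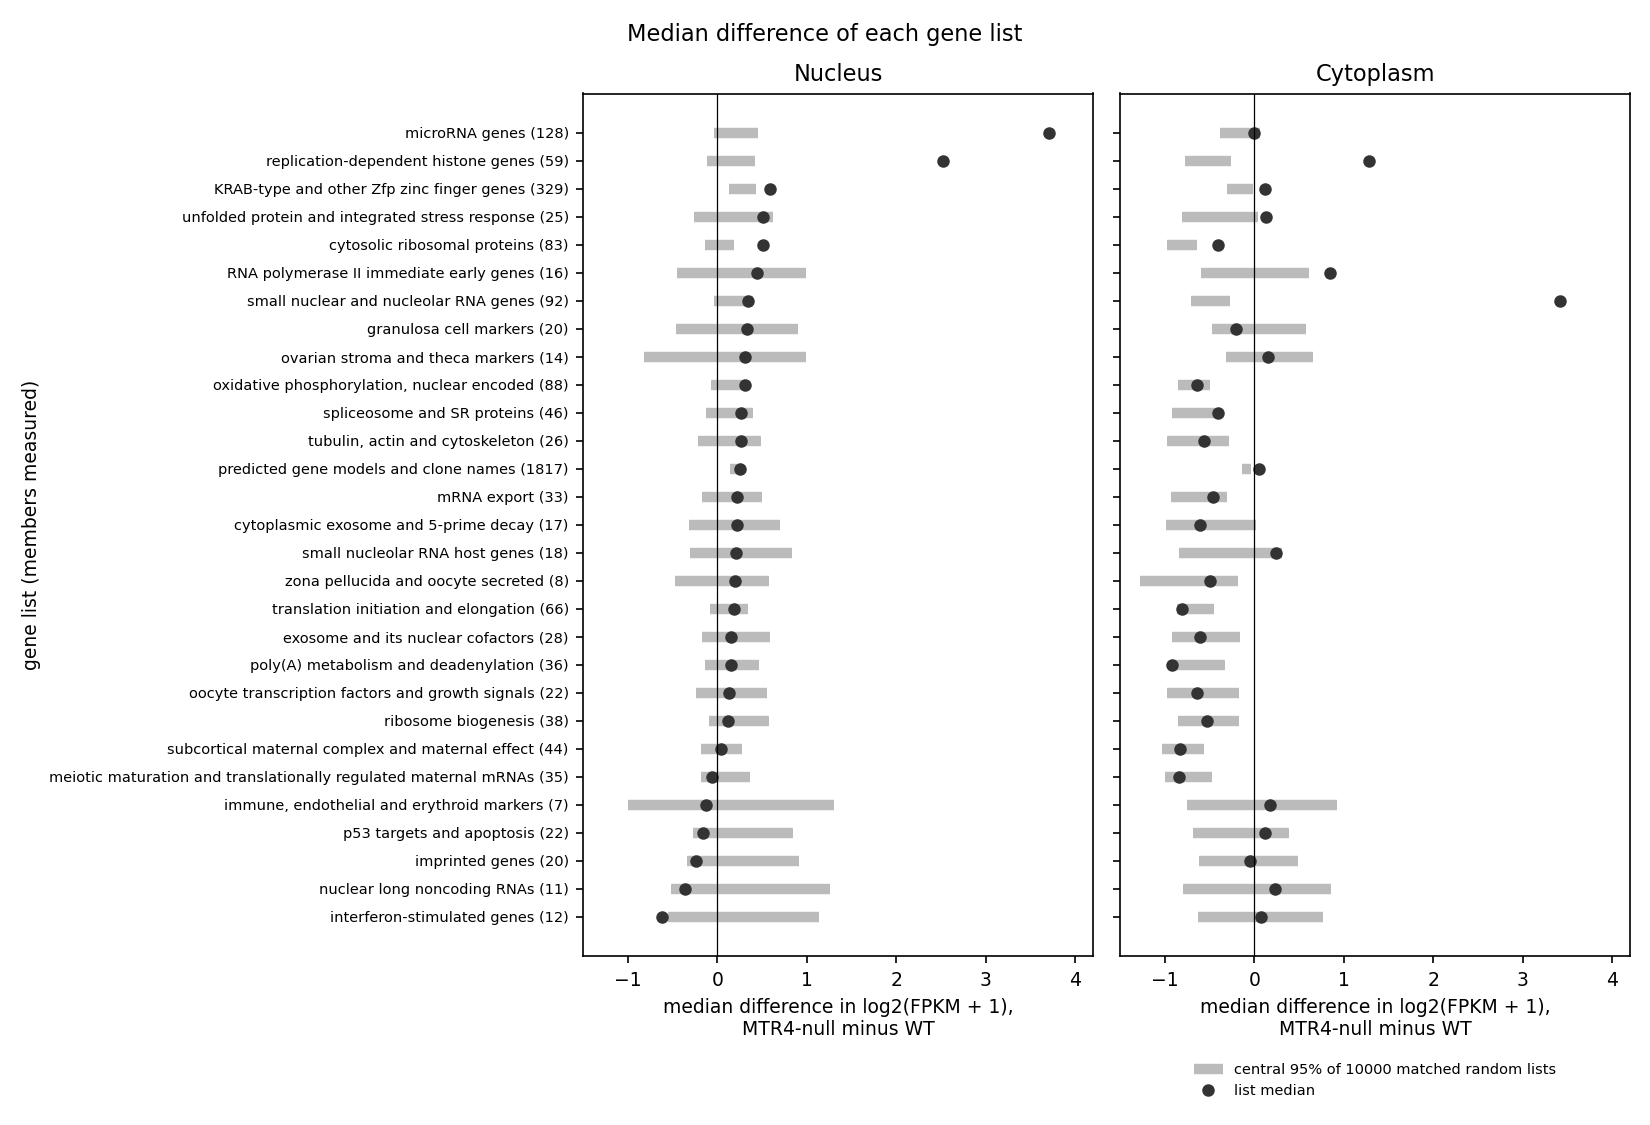
Black points give the median difference in log2(FPKM + 1), MTR4-null minus WT, of each of 29 gene lists, in the nucleus (left) and the cytoplasm (right), with measured members in brackets and grey bars for the central 95% of medians of 10000 random lists matched on mean expression. Histone genes lie above the bar on both sides (2.52 and 1.29), microRNA genes in the nucleus (3.71, but -0.34 over the 36 members above 0 in both columns) and small nuclear and nucleolar RNA genes in the cytoplasm (3.42).

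Nucleus and cytoplasm of WT oocytes were compared to see which RNAs are relatively nuclear. Small nuclear and nucleolar RNA genes were the clearest group: 61 of 92 were at least 2-fold higher in the nucleus and 0 lower, with a median of 5.61 at percentile 100. Of these genes 39 were listed at 0 in the cytoplasm alone, and the 22 above 0 in both columns were all at least 2-fold higher in the nucleus. Nuclear long noncoding RNAs had a median of 1.44, with 7 of 11 higher and 0 lower. Malat1 was at 181 FPKM in the nucleus and 8.63 in the cytoplasm, and Kcnq1ot1, the antisense RNA of an imprinted domain, at 16.05 and 0.11. Host genes of small nucleolar RNAs (median 0.95, 9 of 18 higher), imprinted genes (0.44, 7 of 20 higher) and interferon-stimulated genes (0.90, 6 of 12 higher) also lay above matched lists. Histone mRNAs were relatively cytoplasmic, with a median of -0.60 at percentile 0 and 19 of 59 at least 2-fold lower in the nucleus. Leaving aside gene models and small RNA symbols, the largest nuclear genes were AF357425, Terc at 455 FPKM against 1.32, Zfp488 at 200.3 against 0.356, Olfr856-ps1 at 179 against 0.277, and Rprl3, a copy of the RNase P RNA, at 7829 against 58.9. The largest cytoplasmic ones on the same terms were Bfsp1 (listed at 0 in the nucleus), Rnaset2a (below 0.001 FPKM there), Arl8a at 14.2 FPKM against 0.83, Lzts1 at 19.12 against 1.46, and Hist1h2bj at 56.6 against 6.61. In total 1775 genes were higher and 672 lower in the nucleus. Rescaling the columns to equal sums, which small RNAs dominate, reversed this split to 1183 higher and 6774 lower.

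In MTR4-null oocytes 2428 genes were at least 2-fold higher in the nucleus than in the cytoplasm and 262 lower, with a median log2 difference of 0.52 over all genes. After centring the counts were 603 and 955, so the one-sided split rests on scaling. Small nuclear and nucleolar RNA genes were still higher in the nucleus, with 59 of 92 at least 2-fold higher, 9 lower and a median of 2.08 at percentile 100. Of these genes 32 were listed at 0 in the cytoplasm alone, and of the 53 above 0 in both columns 28 were higher and 8 lower, with a median of 1.28. MicroRNA genes had a median of 2.79 at percentile 100, but of 0.33 over the 45 above 0 in both columns. Immediate early genes lay on the cytoplasmic side, with a median of -0.37 at percentile 0. Other than gene models and small RNA symbols, the largest nuclear genes were Rprl3 at 1066.5 FPKM against 61.7, the ribosomal RNA precursor Rn45s (in libraries depleted of ribosomal RNA) at 3040.1 against 181, Rprl2 at 16.9 against 0.443, and Tstd1 at 11.9 against 0.128. Tmsb15b1 was at 10.4 FPKM in the nucleus and listed at 0 in the cytoplasm. With the same genes left aside, the largest cytoplasmic ones were Amd1 at 6.65 FPKM against 0.0456, the protamine gene Prm1 at 8.08 against 0.413, Iqcf1 at 17.4 against 2.21, Hist1h2af at 5.83 against 0.509, and Lars2 at 3039 against 755.

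**Figure D3:**
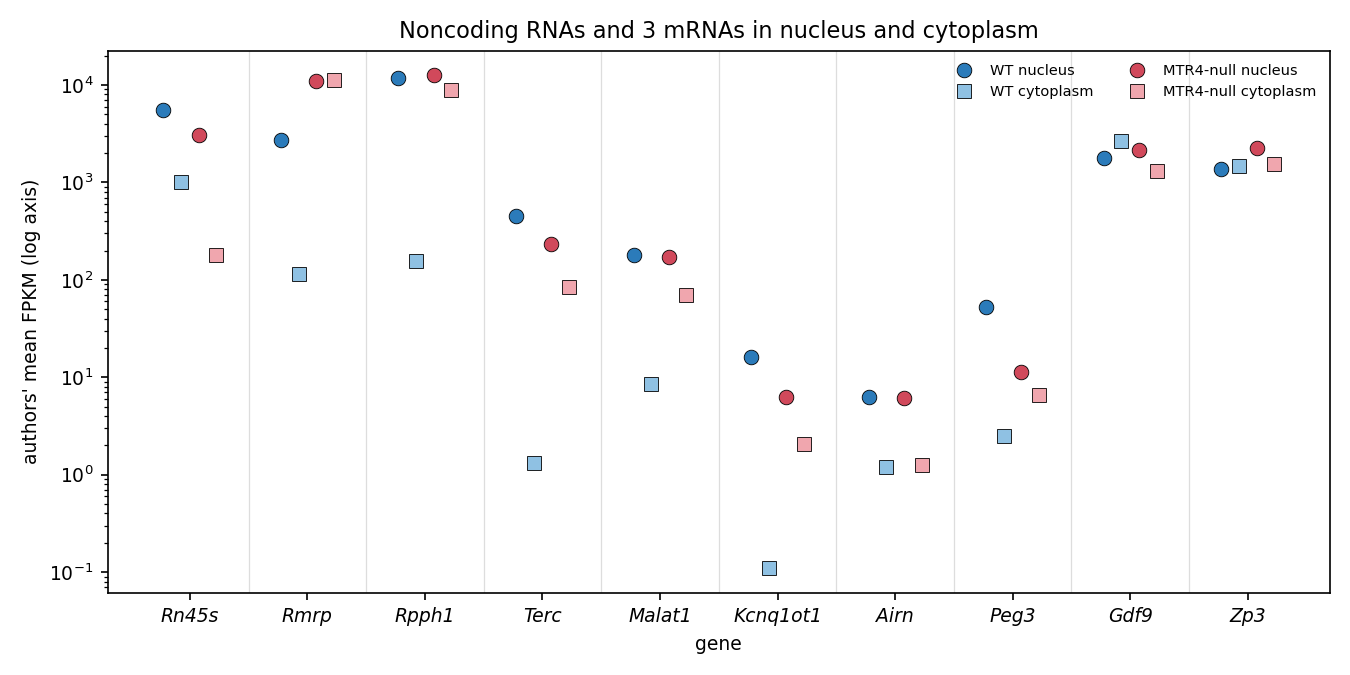
Authors' mean FPKM on a log axis of selected noncoding RNAs, the imprinted mRNA of Peg3 and the oocyte mRNAs of Gdf9 and Zp3, in the nucleus (circles) and cytoplasm (squares) of WT (blue) and MTR4-null (red) oocytes, for genes chosen after their values were seen. Malat1 was at 8.63 FPKM in the WT cytoplasm and 69.6 in the MTR4-null cytoplasm, while Airn was at 1.20 and 1.26 there.

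The ratio of nucleus to cytoplasm differed between the genotypes in opposite ways for different RNA classes. For small nuclear and nucleolar RNA genes the log2 ratio was lower in MTR4-null by a median of 3.06 (the difference was -3.06, at percentile 0), with 57 of 92 at least 2-fold lower and 28 higher. At least 1 value of 0 entered for 73 of them, and of the 19 above 0 in all 4 columns 18 were at least 2-fold lower and 0 higher. Nuclear long noncoding RNAs had a median of -0.60 at percentile 0.66, and Malat1 stood at -2.95, Kcnq1ot1 at -2.69 and Meg3 at -1.98. For histone genes the difference was 1.29 at percentile 100, against 0.57 over all genes, with 34 of 59 higher and 3 lower. Oxidative phosphorylation genes had a median of 0.97 at percentile 99.8. Without gene models and small RNA symbols, the largest single genes toward the nucleus were Bcat2, Tmsb15b1, Gadd45a, Hint2 and Spata24, at 4.74, 4.41, 4.24, 4.17 and 4.04. At the other end were AF357425 at -8.08, which reflects only its nuclear value in WT as it was listed at 0 elsewhere, Terc at -6.14, Rpph1 at -5.72, Olfr856-ps1 at -5.52 and Zfp488 at -5.11. Over all genes 3859 were at least 2-fold higher and 1521 lower, and centring turned these counts to 976 and 3168.

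Averaged over the compartments, 2383 genes were at least 2-fold higher and 1646 lower in MTR4-null (2908 and 1126 after centring). Histone genes had 46 of 59 members higher and 2 lower, with a median of 2.12, small nuclear and nucleolar RNA genes 70 of 92 higher and 14 lower (17 and 2 of the 19 above 0 in all 4 columns, through the cytoplasm), and stress response genes a median of 0.62 at percentile 99.9. Across genes, the log2 differences of the nucleus and the cytoplasm had a Pearson's r of 0.50. Of the genes at least 2-fold higher, 1368 were so in both compartments, against 511 for independent lists, and of those at least 2-fold lower 723, against 374. Nucleus and cytoplasm may have been taken from the same oocytes, so part of this overlap can come from the oocytes sampled. Higher in the nucleus and lower in the cytoplasm were 71 genes, against 730 for independent lists.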

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

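No paired analysis was possible because the deposited columns hold 1 value per group and carry no replicate numbers. For the same reason the planned variance model without trend, replicate blocks, leave-one-out fits, fits on pairs of groups and gene set tests with an estimated correlation or by rotation were not run. Of 60 counts of genes at least 2-fold apart under an alternative, 47 lay within 1.5 times the value reported and 13 did not. With a pseudocount of 5 the counts were 2333 for genotype in the nucleus, 2540 for genotype in the cytoplasm, 602 for compartment in WT, 880 for compartment in MTR4-null, 2311 for the difference of the compartment ratios and 1786 for the averaged genotype comparison, since a larger pseudocount shrinks differences of low genes. With a pseudocount of 0.1 the compartment counts were 4054 in WT and 4281 in MTR4-null. A filter of 5 FPKM left 1373 for compartment in WT, as fewer genes entered. Rescaling to equal sums gave 7957 for compartment in WT, where small RNAs hold 57.7% of the nuclear sum and 4.09% of the cytoplasmic one. For compartment in MTR4-null, quantile normalization gave 1509, centring 1558 and rescaling to the sum without small RNA genes 1549. FPKM of the other genes summed to 410222 in the MTR4-null nucleus and 264137 in its cytoplasm. Rescaling to that sum moved the median log2 difference from 0.52 to 0 and left 855 genes higher and 694 lower. The drop in the count thus follows a shift between whole columns, and why their sums differ was not tested.

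The share of genes higher among those apart moved with scaling. In the nucleus it was 66.1% as reported, 48.0% with quantile normalization and 54.0% with centring. In the cytoplasm it was 41.2%, 49.2% with quantile normalization, 78.1% with centring (60.1% with centring on all genes) and 75.1% with rescaling to the sum without small RNA genes. For compartment in WT it was 72.5%, 52.2% with quantile normalization and 14.9% with rescaling to equal sums. In MTR4-null it was 90.3%, with 50.3% (quantile normalization), 28.3% (equal sums), 38.7% (centring) and 55.2% (sum without small RNA genes) under the alternatives. For the difference of ratios it was 71.7%, then 49.1%, 23.6% and 32.8% with quantile normalization, centring and the sum without small RNA genes, and 84.2% and 81.8% with a pseudocount of 5 and a filter of 5 FPKM, and for the averaged comparison 59.1%, then 50.3%, 72.1% and 71.1% with quantile normalization, centring and the sum without small RNA genes. Among 279 results of named genes none of at least 2-fold was reversed, and none of the 13 list medians outside the central 95%, taken relative to matched lists, changed side in these alternatives. Few reversals were possible, as the genes were picked for large differences. A shift of a whole column also largely cancels out of medians taken relative to matched lists. Interferon-stimulated genes in the nucleus returned inside with 4 of 10 alternatives (both filters at a higher level, no filter and a pseudocount of 5), at percentiles up to 48.0, and splicing factors in the cytoplasm with a pseudocount of 5, at 97.3. Matching on GC content and length too brought immediate early genes and stress response genes in the cytoplasm inside, at 96.1 and 97.1. Read depth limits low genes to an extent that cannot be stated, as the table holds neither counts nor single libraries.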

Other observations

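Several lists that the comparisons above left aside differed little between the genotypes or in both directions. Imprinted genes had a median log2 difference of -0.24 in the nucleus (percentile 5.52), with 1 of 20 at least 2-fold higher in MTR4-null and 5 lower, and -0.05 in the cytoplasm (percentile 56.6), where centring turned it to 0.48. Peg3, a paternally expressed imprinted gene, was at 52.4 FPKM in the WT nucleus, 11.2 in the MTR4-null nucleus, 2.47 in the WT cytoplasm and 6.63 in the MTR4-null cytoplasm. Interferon-stimulated genes had a median of -0.62 in the nucleus, at percentile 1.77, and 0.08 in the cytoplasm, at percentile 58.9. The nuclear value did not hold: 4 of 10 alternatives put the list inside the central 95%, and a filter of 5 FPKM turned the median to 0.53. Eif2ak2, a kinase that senses double-stranded RNA, was at 8.94 and 1.79 FPKM in the WT and MTR4-null nucleus, the nucleic acid sensor gene Zbp1 at 13.3 and 4.40, and Xaf1 at 1.82 and 8.49. Genes of the p53 response and apoptosis had medians of -0.16 (percentile 6.03) and 0.12 (percentile 87.0): Gadd45a was at 0.17 and 11.03 FPKM in the nucleus, Aen at 4.76 and 32.0, and Ddit4 at 95.7 and 22.7 in the cytoplasm.

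Nuclear medians of the remaining lists were 0.51 for stress response genes (percentile 93.3), 0.44 for immediate early genes (percentile 71.0), 0.27 for the cytoskeleton (percentile 79.6), 0.21 for host genes of small nucleolar RNAs (percentile 46.6), -0.36 for nuclear long noncoding RNAs (percentile 5.88) and 0.25 for predicted gene models and clone names (percentile 83.7, and 99.98 for the 1656 annotated ones with GC content and length matched too). In the cytoplasm the models had a median of 0.05 at percentile 100, Zfp genes 0.12 at percentile 100 and microRNA genes 0.00 at percentile 91.1. Pdia6, a chaperone of the endoplasmic reticulum, was at 33.7 and 187 FPKM in the nucleus, Actb at 52.4 and 115, and Pfn1 at 165 and 401. Markers of ovarian stroma (0.31 and 0.15 in nucleus and cytoplasm, percentiles 67.6 and 63.8) and of immune, endothelial and blood cells (-0.13 and 0.18, percentiles 29.3 and 74.9) did not stand apart.

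The tests of read sharing, granulosa cells, carry-over and genomic DNA below were chosen after the values they bear on had been seen. Predictions for those of length and GC content and of short genes were written before their own values. Matching on length and GC content was still added after the data had been seen. The first pattern is that of the histone genes in the MTR4-null nucleus. Reads moving between near-identical histone genes would leave their sum alike, but the summed FPKM was 3.59 times as high as in WT. Lists matched on length, GC content and expression had a median of 0.40 against 2.52 for the histones, at percentile 100, although their median length was 815 nt against 534 nt. Dividing granulosa cells in the MTR4-null samples could not be excluded: their markers had a median of 0.33, with a 95% interval from -0.56 to 1.29 that is taken over the 20 marker genes and not over samples, while Inha, at 21.4 and 11.9 FPKM, and Cyp11a1, Inhba and Inhbb were lower. Of the 59 histone genes, 56 have a single exon, and the matched lists were not matched on exon number. The 296 other coding genes with a single exon, described below, had a median of 1.07 in the nucleus, with 155 higher and 38 lower. A difference by gene structure was therefore not separated from a difference of histone genes. An effect of MTR4 loss on histone RNA may account for the pattern. This effect stays a hypothesis that these columns do not test, as no replicates are at hand.

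The second pattern is the signal of small nuclear and nucleolar RNAs in the MTR4-null cytoplasm. To ask whether it rests on genes too short for FPKM, members of at least 300 nt were taken alone: their median was 4.87, but there were only 5, with Rpph1, Scarna2 and Terc higher, Scarna10 at 42.7 and 0, and Rprl1 listed at 0 in both, so short genes cannot be told apart from a wider difference. Nuclear content carried into the cytoplasm samples during micromanipulation would bring abundant nuclear RNAs in 1 ratio. Among 39 abundant members above 0 in the MTR4-null cytoplasm, the ratio of MTR4-null cytoplasm to nucleus went from 0.0225 (Scarna3a) to 3.19 (Snord23), a spread of 142 times. Members listed at 0 in that cytoplasm, such as Scarna10 at 711 FPKM in the MTR4-null nucleus, were left out of this spread. Other nuclear RNAs went both ways: Malat1, Kcnq1ot1, Meg3 and Rmrp were higher in the MTR4-null cytoplasm, Airn and Rprl3 were alike, and Rn45s was at 1016 FPKM in WT and 181 in MTR4-null. As the libraries were depleted of ribosomal RNA, the Rn45s values can also depend on that step. With no error on any of these values, carry-over and a biological difference cannot be told apart.

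The third pattern is a difference by gene structure, noticed in the data. Of 296 coding genes with a single exon, other than histones, 155 were at least 2-fold higher in the MTR4-null nucleus and 38 lower, with a median of 1.07, against 0.19 for 12639 genes with more exons, of which 21.8% were higher. Mocs3 was at 2.80 and 88.7 FPKM, Irf2bp1 at 3.27 and 85.0, Mgat2 at 1.34 and 38.0, and Exosc6, Junb and Jund belong to the same class. Multi-exon lists matched on length, GC content and expression had a median of 0.29, which left the single-exon genes at percentile 100, so these properties do not account for it as a whole. Genomic DNA as the whole cause would raise silent genes alike. The gain of 1352 olfactory, vomeronasal and taste receptor genes had a median of 0 and a central 95% that ended at 0.298 FPKM. The median gain of the single-exon genes was 2.55 FPKM. The receptors entered without the filter of 1 FPKM that the single-exon genes had passed, so these gains are not on equal terms. Not all receptors were silent in WT: their summed FPKM was 744 in the WT nucleus and 271 in the MTR4-null nucleus, with 243 gaining and 156 losing. At 0 were 1163 receptor genes in WT and 1011 in MTR4-null, so a share of DNA stays open. Across 12993 coding genes the log2 difference also fell with exon number, at a Spearman's rho of -0.17 in the nucleus and -0.24 in the cytoplasm. Whether it fell among multi-exon genes alone was not examined, so the pattern may not be particular to unspliced transcripts. A candidate explanation is that transcripts made without splicing differ in their handling without MTR4, in the cytoplasm too (median 0.55, matched lists -0.07, percentile 100), and these 4 columns do not test it further.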
